A study of Rattus norvegicus with 8 samples.

How the data were processed

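Liver messenger RNA of 4 control rats and 4 PFOS rats was measured on two-colour Agilent SurePrint G3 rat expression arrays. Groups came from the sample labels, which name separate animals, and replicate numbers within a group were given in accession order and pair nothing. Per the labels, sample RNA was labelled with Cy5 and a universal rat reference RNA with Cy3 on every array, so the ratios of all arrays run in 1 direction and no dyes were swapped. The scanner files hold spot intensity values that the authors deposited as extracted with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. They give the median signal and median local background of each spot in both channels, on a linear scale, and processed signals that the software had already corrected for background and dye. Per the file headers the scan resolution was 3 micrometres, which differs from the series' design text. The authors' deposited value table holds log2 ratios, with the method not given in the sources used here. Its columns correlated with the log2 ratio of Cy5 over Cy3 without background subtraction at 0.995 to 0.997, with slopes of 0.989 to 0.993. Its scale and direction were read from that comparison. Its medians per array, in the order control 1 to 4 and PFOS 1 to 4, were -0.048, -0.054, -0.052, -0.057, -0.052, -0.061, -0.061 and -0.053, and how it was centred is unknown.

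Each array had 62976 spots, of which 4259 were control spots, and 30367 probes, of which 13137 had 1 spot, 15840 had 2 and 1390 had 10. The plan had named mean signals. The files held median signals and no mean signals, so medians were used. Background was corrected with normexp at an offset of 50 on all spots, and each array was normalized by loess with control spots at weight 0. Spots that the software marked as outliers were left out (733 to 991 per array), no spot was marked saturated, and the spots of a probe were averaged. The scanner files name probes by accession. Of 19131 probes with a curated RefSeq transcript accession, 17933 were matched, without versions, to a symbol in a RefSeq gene table of the GRCr8 assembly, and 18004 of all probes had 1 of 15154 symbols. The other 12363 probes keep the files' names. The arrays' grid was drawn for an older build, so no coordinates are given. Probes well above background in Cy5 on at least 4 of 8 arrays were kept (16952), and of several probes of a gene the one with the highest mean Cy5 signal stood for it, which left 15200 genes and features, 9618 with a symbol. Among 1607 genes with several tested probes, the probes of 54 disagreed on the call, and none had called probes of opposite sign.

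The groups were compared on the log2 ratio with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with two-sided p-values adjusted by the Benjamini-Hochberg method. Tables were read with data.table (version 1.17.8) and jsonlite. A log2 change is PFOS minus control, and a fold is 2 to its power. Where a probe was not well above background on any array of a group, the fold is a bound. The brighter group's mean Cy5 value was set against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. This used the Cy5 channel after loess and Aquantile and is open to dye bias, since no dyes were swapped. Of the called features, 18 were not well above background on any array of 1 group. Before the data were examined, 37 gene lists and the rule for named genes were fixed. The rule takes, among called genes with a symbol whose groups do not overlap, the 12 largest rises and 12 largest falls, then up to 4 tested members of each list with the smallest p, and a few genes whatever their p, among them Cyp4a1, Cyp2b1, Cyp7a1, Dio1 and Thrsp. Results withheld for evaluation are left out of the text. It named 157 genes, of which 63 were called. Other genes in the text, such as Ehhadh, Pklr, Crat, Crot, Alas1, Por, Decr1, Scp2, Cyp3a23-3a1, Cyp3a62, Thra and Me1, were chosen after their values were seen. Lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and with fry, and adjusted over lists. Aldh1a7 and Hba1 were written in the lists but not resolved to a symbol.

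The alternatives were no background subtraction, normexp with offset 0, processed signals, median centring, scaling between arrays, the Cy5 channel alone, the authors' value table, 3 other filters on dim probes, a minimum fold, the mean of a gene's probes, eBayes with trend and robust options, array weights, slide row or column as a block and each array left out. The 2 slide rows taken alone were added after the data were seen.

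The steps were tested on simulated data. Log2 ratios of 15200 genes were drawn with the spread of the real arrays after normalization, independently for each gene. The shares called thus do not show the effect of normalization or of genes that vary together. Of 50 genes raised by 0.5 on the log2 scale 52% were called, of 50 raised by 1 88%, of 50 lowered by 1 90% and of 50 raised by 2 98%, and 2.96% of the calls were unchanged genes. When the net Cy5 signal of 200 probes was multiplied by 4 in copies of the control arrays, a log2 change of 2, the median measured change was 1.85 in the brighter part and 1.64 in the dimmer part of them. Changes are thus understated, more so for dim probes. An offset can pull ratios together, but its part in this was not tested.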

Results

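The series measured messenger RNA in the liver of adult male Sprague-Dawley rats that ate a control diet or a diet with 50 mg/kg of potassium perfluorooctanesulfonate (PFOS), a fluorinated surfactant, for 28 days. Its title names liver microRNA and thyroid hormone balance as the subject, and these arrays are the messenger RNA part. Each group held 4 rats, each with its own array, so that 8 two-colour arrays were compared. Liver RNA was in the Cy5 channel, and a commercial pool of rat RNA was in the Cy3 channel of every array as a common reference. The median Cy5 brightness of a spot was 116 to 160 units per array, over a local background of 71 to 75 units. Between 50.3% and 59.1% of the 30367 probes were well above background in Cy5. All arrays came from 1 slide and 1 scan date, so neither could be a batch. The 4 arrays of 1 slide row, 2 from each group, had Cy5 medians of 154.5 to 160, and those of the other row, again 2 from each group, had 116 to 138. Log2 ratios correlated across probes at 0.980 to 0.983 between control arrays, at 0.972 to 0.981 between PFOS arrays and at 0.958 to 0.974 between groups. The first principal component held 37.5% of the variance, with the control arrays at -26.3 to -15.2 and the PFOS arrays at 10.4 to 25.7. The number of arrays limits the precision, and the median standard error of a log2 change was 0.11.

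The comparison of both diets asks which liver transcripts PFOS changed. Of 15200 genes and unnamed features tested, 602 differed between the groups (limma, Benjamini-Hochberg adjusted p under 0.05), 277 higher and 325 lower in PFOS. Of these, 139 changed by at least 2-fold, 80 up and 59 down, and 23 rose by at least 4-fold while 12 fell by at least 4-fold. A gene symbol was known for 416 of the changed features. The values of both groups did not overlap for 1945 of all tested genes (12.8%), against 2.86% expected by chance, and for 600 of the 602, which the test selects for separation. The count was 239 with median centring in place of loess, 268 with slide column as a block and 343 where a change of at least 1.5-fold was also required. It was between 350 and 387 without control 1, control 2, control 3, PFOS 1, PFOS 2 or PFOS 3, while 92 and 29 genes were called within the slide rows, which hold 2 arrays of each group.

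**Figure D1:**
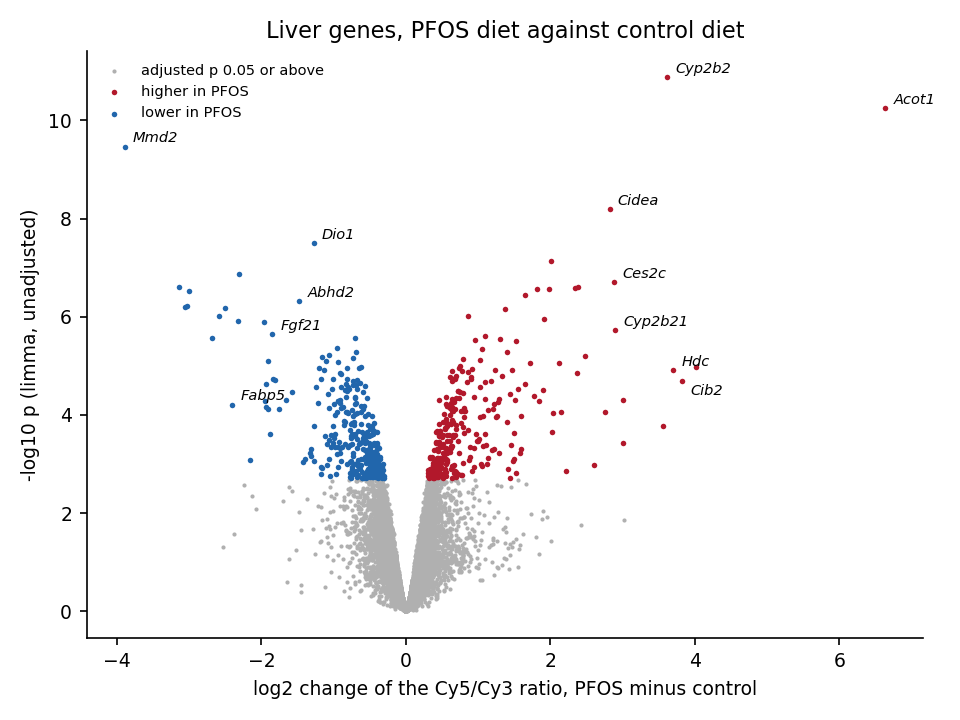
The log2 change of each tested gene's Cy5/Cy3 ratio, PFOS minus control, on the x axis is set against the unadjusted limma p on a -log10 scale on the y axis. Each point is 1 of 15200 genes or features, coloured where the adjusted p was under 0.05, and Acot1 (6.63) and Mmd2 (-3.89) lie at the ends of the x axis among the named genes.

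The largest rise among genes with a symbol was that of Acot1. This gene, for a cytosolic acyl-CoA thioesterase, rose 99.2-fold, from a log2 ratio of 0.60 ± 0.46 (SD, n = 4) to 7.24 ± 0.09 (SD, n = 4), with a log2 change of 6.63 (SE 0.20, limma adjusted p = 4.3e-07). It was well above background on 3 of the 4 control arrays, and its log2 change was 5.17 with median centring in place of loess. Cyp2b2, a cytochrome P450 of drug metabolism, rose 12.2-fold (log2 change 3.62, SE 0.09, limma adjusted p = 2.02e-07). A second Cyp2b2 probe changed by 0.75 and did not pass, so the size depends on the probe, and the planned settings gave 2.18 to 5.74. Ugt2b1, a glucuronosyltransferase, rose 8.05-fold (3.01, SE 0.55), and its call was lost without control 1, PFOS 1 or PFOS 3, with changes of 2.40 to 3.49 over the left-out arrays. Ces2c, a carboxylesterase, rose 7.36-fold (2.88, SE 0.21). Cyp2b21 was not well above background on any control array and was at least 5.43-fold higher in PFOS under loess and Aquantile, while its Cy5 channel alone, quantile normalized, gave 4.18-fold and the planned settings log2 changes of 1.86 to 6.83. Cidea, a lipid droplet protein, rose 7.05-fold (2.82, SE 0.14), Vnn1, a pantetheinase, 5.16-fold (2.37, SE 0.29) and Eci1, an enoyl-CoA isomerase of fatty acid oxidation, 5.06-fold (2.34, SE 0.18). Cib2, a calcium-binding protein, rose 14.1-fold (3.82, SE 0.48) and Hdc, the histamine-forming decarboxylase, also rose (3.70, SE 0.44). Colq, the collagen tail of acetylcholinesterase, rose 5.23-fold (2.39, SE 0.18) and was well above background on 1 control array, with log2 changes of 1.43 to 4.54 over the planned settings. Tsku, a secreted proteoglycan, rose 6.09-fold (2.61, SE 0.55, limma adjusted p = 0.0358), and this call was lost without control 3, control 4 or any 1 PFOS array, with changes of 2.22 to 3.03, and in 3 other settings.

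The largest falls among genes with a symbol began with Mmd2, which was well above background on all 4 control arrays and on no PFOS array and was at least 9.82-fold lower in PFOS under loess and Aquantile and 6.30-fold lower in the quantile-normalized Cy5 channel alone (log2 ratio 3.83 ± 0.26 against -0.06 ± 0.17, SD, n = 4 each, limma adjusted p = 1.73e-06). Fabp5, a fatty acid-binding protein, fell 5.29-fold (log2 change -2.40, SE 0.35) and Tsc22d1, a transcriptional regulator, 3.90-fold (-1.96, SE 0.18). Clec2d2l1 fell 3.82-fold (-1.93, SE 0.28), and Slc16a11, of the monocarboxylate transporter family, 3.68-fold (-1.88, SE 0.33). Fgf21, a hormone secreted by the liver, fell 3.61-fold (-1.85, SE 0.18, limma adjusted p = 0.00127) and was well above background on 3 of the 4 PFOS arrays, with a log2 change of -1.14 in the Cy5 channel alone. Il17rb, an interleukin receptor, fell 3.37-fold (-1.75, SE 0.26, and -1.14 in the Cy5 channel alone), Reg4, a secreted lectin, 3.17-fold (-1.66, SE 0.23) and Abhd2, a lipid hydrolase, 2.79-fold (-1.48, SE 0.12). Reg4 did not pass with the scanner software's processed signals, at -0.96. Prss32, a serine protease (-1.32, SE 0.26), Or9s13, an olfactory receptor (-1.32, SE 0.26), and Vxn (-1.31, SE 0.25) completed the 12. Over the planned settings Mmd2 was at -6.76 to -2.64, Prss32 at -2.39 to -0.82, Or9s13 at -1.32 to -0.18 and Vxn at -2.66 to -0.78. Prss32 was lost without control 1, control 2 or any 1 PFOS array, at -1.56 to -1.14 over the left-out arrays, and with slide column as a block. Or9s13 was lost without control 1, control 3, control 4, PFOS 2 or PFOS 3, at -1.48 to -1.09, and in 4 other settings, among them the authors' value table. Vxn was lost without control 2, control 3, PFOS 1, PFOS 2 or PFOS 3, at -1.58 to -1.10, and its second probe changed by -0.25 without a call.

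For 37 gene lists fixed before the data were examined, the members' changes were set against those of all other genes with camera at a preset correlation, for the 35 lists with at least 3 tested members. Of these, 12 passed at an adjusted p under 0.05, 6 up and 6 down, and none with an estimated correlation, where the smallest adjusted p was 0.0721. The directional fry test, which asks whether a list's genes move one way on balance, called 10 lists. Of the 35 ways to part the 8 arrays into 4 and 4, 6 gave at least 12 shifted lists, the real one included. For peroxisomal fatty acid oxidation, mitochondrial fatty acid oxidation, PPARA targets and CAR and PXR targets, the real split gave the smallest camera p of the 35 splits. For the other 8 lists that passed, between 3 and 11 splits gave a p as small. With processed signals 6 of the 12 lists did not pass, those of fatty acid synthesis, apolipoproteins, female-biased genes, glucose metabolism, hepatocytes and endothelium.

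Genes that the nuclear receptors CAR and PXR induce, mostly enzymes of drug metabolism, shifted upward as a list, with 12 of 20 tested members higher, none lower and 8 not called (median log2 change 1.02, camera adjusted p = 4.25e-15, adjusted p = 0.0721 with an estimated correlation). Adjusted over the list alone, 13 were higher. Beside Cyp2b2, Ces2c and Ugt2b1, Aldh1a1, a retinal dehydrogenase, rose by 1.82 (SE 0.14) on the log2 scale and Ugt1a6, which glucuronidates phenols, by 1.59 (SE 0.25). Alas1, the first enzyme of heme synthesis, rose by 1.56 (SE 0.21), Por, the electron donor of microsomal P450 enzymes, by 1.12 (SE 0.21) and Gadd45b by 1.05 (SE 0.11). The P450 enzymes Cyp3a23-3a1 (1.46, SE 0.27), Cyp3a2 (0.99, SE 0.18) and Cyp3a62 (0.94, SE 0.20) also rose. Cyp3a2 lost its call without PFOS 1 or PFOS 3, at 0.82 to 1.10 over the left-out arrays, and in 3 settings, with 0.27 under processed signals. Cyp2b1 was not analysed here, since no tested probe carried its name. Near-identical genes such as those of the Cyp2b, Cyp3a, Ugt1a and Acot families can bind one another's probes, so each of their values is uncertain as to the gene.

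Peroxisomal fatty acid oxidation shifted upward, with 11 of 23 tested members higher, 1 lower and 11 not called (median 0.43, camera adjusted p = 2.17e-12, adjusted p = 0.0721 with an estimated correlation), and with 14 higher and 1 lower adjusted over the list alone. Ech1 rose 3.74-fold (1.90, SE 0.17), the carnitine acyltransferases Crat and Crot rose by 1.83 (SE 0.26) and 1.77 (SE 0.24) on the log2 scale, and the thiolase Acaa1b by 1.65 (SE 0.13). Scp2, a sterol carrier and thiolase, fell by 0.36 on the log2 scale in the ratio (SE 0.08), with a Cy5 change of -0.13 and a Cy3 change of 0.17. Mitochondrial fatty acid oxidation and ketogenesis shifted the same way, with 11 of 23 members higher, none lower and 12 not called (median 0.39, camera adjusted p = 1.26e-12, adjusted p = 0.0721 with an estimated correlation), and 15 higher adjusted over the list alone. Beside Eci1, Acot2 rose by 1.72 (SE 0.20), Decr1 by 1.22 (SE 0.18), Acat1 by 0.75 (SE 0.10) and Cpt2, which releases fatty acids from carnitine inside mitochondria, by 0.73 (SE 0.10). Omega-oxidation and other targets of the fatty acid receptor PPARA shifted upward with 8 of 27 members higher, 1 lower and 18 not called (median 0.27, camera adjusted p = 1.76e-06, adjusted p = 0.0721 with an estimated correlation). Adjusted over the list alone, 13 were higher and 2 lower. Acot1, Cidea and Vnn1 led it, and Pex11a, a peroxisome division factor, rose by 1.51 (SE 0.21), while Fgf21 was its called fall. In the peroxisome assembly list, Pex11a was the 1 called gene of 15, with 2 higher adjusted over the list alone, and the list did not pass (camera adjusted p = 0.296).

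The Cy3 reference channel, which should not differ with diet, moved with the Cy5 channel for a few genes. Their ratios thus changed less than their Cy5 signal. In the Cy3 channel alone 12 genes were called, all with Cy5 changes of the same sign. Cyp4a1, the fatty acid omega-hydroxylase, rose by 0.72 (SE 0.13, limma adjusted p = 0.0191) in the ratio and by 2.54 (SE 0.15) in the Cy5 channel alone, where its Cy3 signal rose by 1.64. With processed signals its ratio changed by -0.005 and was not called, and it was also lost in 4 other settings and without control 2 or PFOS 3. Ehhadh, the peroxisomal bifunctional enzyme, rose by 0.47 in the ratio and by 2.83 in Cy5. Cyp2b2 rose by 5.74 in Cy5, Acot2 by 2.44, Aldh1a1 by 2.56, Ephx1, an epoxide hydrolase, by 1.56 against 0.92 in the ratio, and Cyp3a2 by 1.95. Apoa1, the main protein of high-density lipoprotein, was not called in the ratio at -0.38 and fell by 1.79 in Cy5 (limma adjusted p = 0.000168). Pklr, liver pyruvate kinase, was at -0.13 in the ratio and fell by 1.65 in Cy5. Of the other named genes not called in the ratio, Cy5 alone called Cyp8b1, of bile acid synthesis (-1.12 against -0.51 in the ratio), the acute phase protein Crp (0.88 against 0.36), Mbl1 (-0.48 against -0.29), Lcat (-0.46 against -0.34), the coagulation inhibitor Serpind1 (-0.42 against -0.40) and Pex7 (0.35 against 0.30). Of 261 genes with a mean log2 ratio of 6 and above, the ratio called 25 and the Cy5 channel alone 49.

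**Figure D2:**
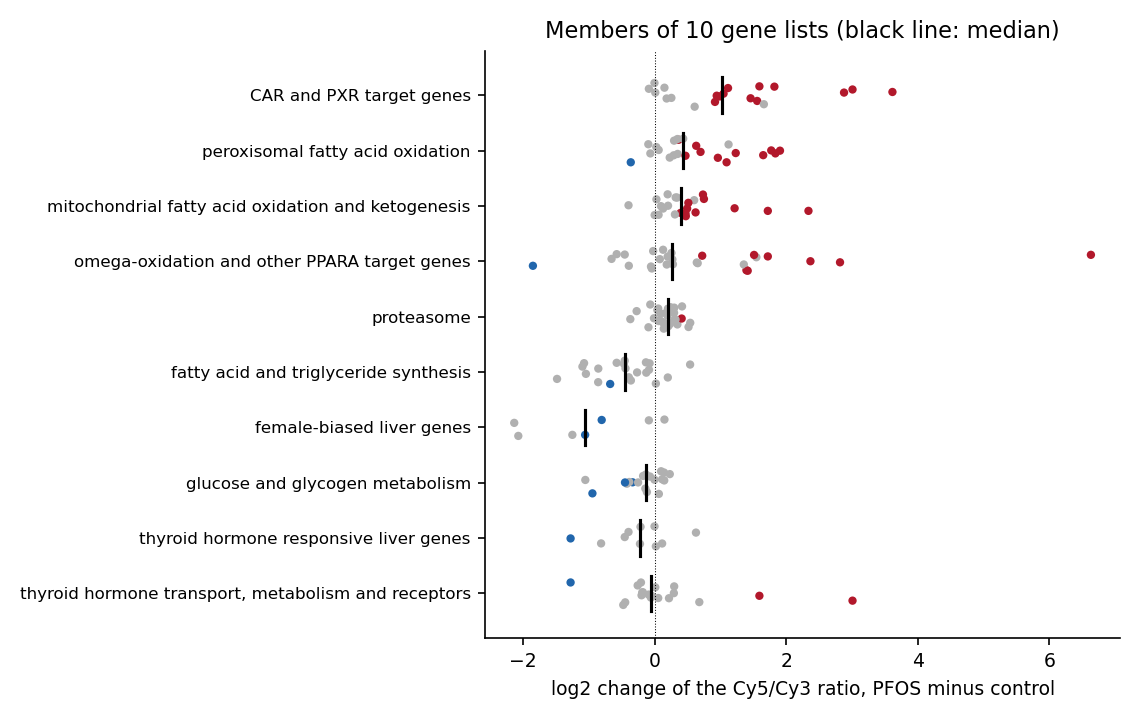
Each point is a tested member of the gene list named on the y axis, placed at its log2 change of the Cy5/Cy3 ratio, PFOS minus control, with called rises red, called falls blue and the other members grey. Black lines mark medians, which run from 1.02 for CAR and PXR targets to -1.06 for female-biased genes, and points are spread vertically for legibility.

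Fatty acid and triglyceride synthesis shifted downward, with 1 of 21 tested members called, the triglyceride-forming enzyme Dgat2 (-0.68, SE 0.13, limma adjusted p = 0.0226), and 18 of 21 values below 0 (median -0.44, camera adjusted p = 0.00132, adjusted p = 0.543 with an estimated correlation). Adjusted over the list alone, 4 were lower. Not called were Fasn, fatty acid synthase (-1.48, SE 0.45), Acaca, acetyl-CoA carboxylase (-0.86, SE 0.23), and Gpam (-0.86, SE 0.26). Dgat2 lost its call without control 1, PFOS 2 or PFOS 3, at -0.75 to -0.57 over the left-out arrays, and with median centring or slide column as a block. The list did not pass in fry (adjusted p = 0.182). Apolipoproteins and lipoprotein handling shifted downward with 2 of 19 members lower in both counts, over all genes and adjusted over the list alone. These were Lipc, hepatic lipase (-0.50, SE 0.09), and Apoc2 (-0.38, SE 0.08), and the list had a median of -0.19 (camera adjusted p = 0.0168, adjusted p = 0.501 with an estimated correlation). Apoc2 lost its call without any 1 array but control 3 and in 6 settings, at -0.11 after scaling between arrays, and Lipc without control 1, control 2, control 4, PFOS 1 or PFOS 3 and in 3 settings, at -0.31 after that scaling. The list's shift was lost without control 1 or PFOS 3 and in 5 more settings, and its median was 0.03 after scaling between arrays. Of 25 cholesterol genes, Hmgcs1 rose (0.81, SE 0.13), a call lost with slide column as a block, and 1 was higher and 1 lower adjusted over the list alone, while the list did not pass (camera adjusted p = 0.495). No member of 17 for bile acid synthesis and transport was called in the ratio, nor adjusted over the list alone (camera adjusted p = 0.474), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, changed by -0.82 (SE 0.36, limma adjusted p = 0.246).

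Among genes of thyroid hormone transport, metabolism and receptors, Dio1, the deiodinase that activates thyroxine in liver, fell 2.43-fold, from 6.03 ± 0.08 (SD, n = 4) to 4.75 ± 0.07 (SD, n = 4), with a log2 change of -1.28 (SE 0.08, limma adjusted p = 9.56e-05), which was -0.75 with processed signals and remained called. Ugt1a6 and Ugt2b1, of the enzyme families that glucuronidate thyroid hormones, rose as given above. Of 19 tested members 2 were thus higher, 1 lower and 16 not called, with 3 higher and 2 lower adjusted over the list alone, and the list as a whole did not pass (median -0.06, mean 0.14, camera adjusted p = 0.758, with a downward direction). Not called were the deiodinase Dio3 (0.68, SE 0.17, limma adjusted p = 0.0693), which was well above background on 2 control arrays, the plasma carrier Ttr (-0.45, SE 0.14, with a Cy5 change of 0.02 and a Cy3 change of 0.52) and the receptor Thra (-0.09, SE 0.10). Ugt1a1, Serpina7 and Thrb were not analysed here. Among 10 liver genes that respond to thyroid hormone, Dio1 was the 1 called, also adjusted over the list alone. The list did not pass in camera (median -0.22, camera adjusted p = 0.142) and passed downward in fry (adjusted p = 0.0162), with median centring and in the Cy5 channel alone. Thrsp, a classic thyroid hormone target, changed by 0.02 (SE 0.08) in the ratio. Its Cy5 signal changed by -1.12 (SE 0.35, limma adjusted p = 0.113) and its Cy3 signal by -1.02 (SE 0.30), neither of them called. The ratio of Thrsp thus does not bound its change. Klf9 (0.63, SE 0.24) and Me1, malic enzyme (-0.46, SE 0.43), did not pass.

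**Figure D3:**
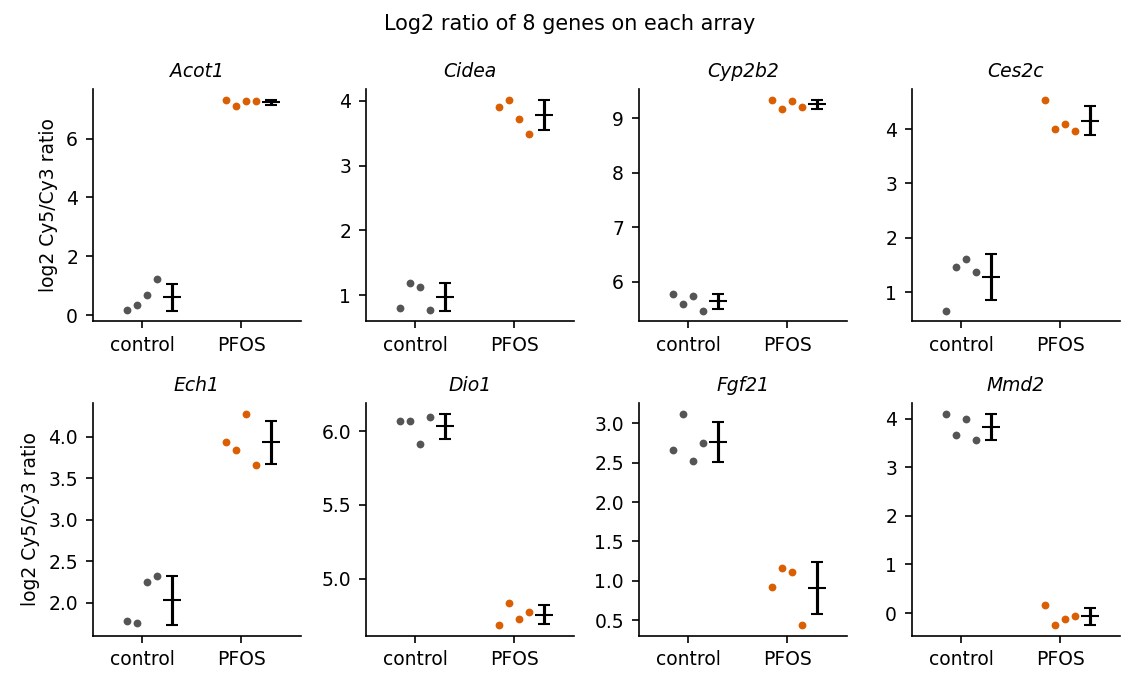
The log2 Cy5/Cy3 ratio of 8 genes on the y axis is shown for each of the 4 control and 4 PFOS arrays, with the bar beside them at the mean ± SD (n = 4). The groups do not overlap for any of the 8, and Dio1 went from a mean of 6.03 to 4.75; each y axis has its own range and does not start at 0.

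Sexually dimorphic liver genes were tested because these rats were male. The female-biased list shifted downward (median -1.06, camera adjusted p = 0.00593, adjusted p = 0.483 with an estimated correlation), with 2 of 7 members lower, and 4 adjusted over the list alone, and was lost where Cy3 also had to be well above background. The 2 were Sult2a1, a hydroxysteroid sulfotransferase (-1.06, SE 0.19), and Srd5a1, a steroid 5-alpha-reductase (-0.81, SE 0.15). Sult2a1 fell by 2.14 in the Cy5 channel alone but changed by 0.37, not called, with processed signals, and it was lost in 3 other settings and without control 1, control 2 or PFOS 1, at -1.22 to -0.94. Srd5a1 was lost without control 1, PFOS 1 or PFOS 3, at -0.91 to -0.65, and with median centring or slide column as a block. Cyp2c12 (-2.14, SE 0.57) and A1bg (-2.07, SE 0.62) did not pass. Of 12 male-biased genes Cyp3a2 was called, with 1 higher and 1 lower adjusted over the list alone, and Cyp2c11 was at 0.23 (SE 0.09, camera adjusted p = 0.473 for the list).

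Glucose and glycogen metabolism shifted downward (median -0.13, camera adjusted p = 0.0315, adjusted p = 0.501 with an estimated correlation), with 3 of 19 members lower and 5 adjusted over the list alone. Pc, pyruvate carboxylase, fell by 0.95 on the log2 scale (SE 0.10, limma adjusted p = 0.00193), Pygl, glycogen phosphorylase, by 0.45 (SE 0.08) and Eno1, an enolase, by 0.34 (SE 0.08). The shift was lost without control 1, control 2, PFOS 1 or PFOS 3 and in 5 settings, and its median was 0.02 after scaling between arrays. Eno1 was lost without any 1 array but PFOS 2, at -0.38 to -0.32, and in 8 settings, and Pygl in 4 settings, slide column as a block and the Cy5 channel alone among them. None of 37 genes of amino acid catabolism and the urea cycle was called, nor adjusted over the list alone (camera adjusted p = 0.558). In the circadian list Per2 (-0.60, SE 0.14), Nfil3 (-0.42, SE 0.09) and Cry2 (-0.36, SE 0.07) were lower among 13, also adjusted over the list alone. The list passed in fry (adjusted p = 0.0229) and not in camera (adjusted p = 0.142), and each of these calls was lost without most single arrays and in 5 settings for Per2, 9 for Nfil3 and 3 for Cry2. In the endoplasmic reticulum stress list, Asns, asparagine synthetase, rose by 1.33 (SE 0.16), and the chaperones Sdf2l1 (-0.56, SE 0.10) and Dnajc3 (-0.51, SE 0.09) and the degradation factor Sel1l (-0.42, SE 0.09) fell. That made 1 of 22 higher and 3 lower, or 4 and 9 adjusted over the list alone, with camera adjusted p = 0.133 and fry adjusted p = 0.0241 downward. These 3 falls were lost with median centring and with slide column as a block. Scaling between arrays also ended the calls of Dnajc3 and Sel1l. Sel1l was further lost with normexp at offset 0, processed signals, the Cy5 channel alone, eBayes with trend and robust options and slide row as a block. Sdf2l1 was lost without control 1 or PFOS 1, Dnajc3 without control 1, PFOS 2 or PFOS 3 and Sel1l without any 1 array but PFOS 3.

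Proteasome subunits shifted upward by a small amount (median 0.20, camera adjusted p = 3.85e-07, adjusted p = 0.342 with an estimated correlation), with 32 of 37 values above 0. Psmc2 (0.41, SE 0.09) was the called member, lost without any 1 array but PFOS 3, and 7 were higher adjusted over the list alone. Cytosolic ribosomal proteins shifted upward by less (median 0.06, camera adjusted p = 0.0203, adjusted p = 0.735 with an estimated correlation), with 1 of 72 higher, Rps26 (0.35, SE 0.07), whose call was lost without any 1 array, and none adjusted over the list alone. That shift was lost without control 4, PFOS 1 or PFOS 3, after scaling between arrays, in fry and in the Cy5 channel alone. Of 68 oxidative phosphorylation genes Uqcrh fell (-0.33, SE 0.07), a call lost without any 1 array, with none adjusted over the list alone (camera adjusted p = 0.474). Of 21 NRF2 targets, Akr7a3, an aldo-keto reductase (1.21, SE 0.18), and Ephx1 rose and Osgin1 fell (-0.81, SE 0.17), with 3 higher and 1 lower adjusted over the list alone. The list did not pass (median -0.07, mean 0.02, camera adjusted p = 0.474), and Osgin1 was lost in 3 settings and without 6 single arrays. Of 5 AHR targets Ugt1a6 rose, 2 were higher adjusted over the list alone, and Cyp1a2 was at -0.33 (SE 0.15, camera adjusted p = 0.201 for the list). Of 29 cell cycle genes Rrm2, a ribonucleotide reductase subunit, fell (-0.69, SE 0.15), also adjusted over the list alone, and lost its call without any 1 array but PFOS 4. The cell cycle list did not pass (median -0.10, camera adjusted p = 0.0882) but passed downward in 8 settings. None of 16 p53 targets (camera adjusted p = 0.936), 21 acute phase proteins (0.616) or 15 coagulation factors (0.296) was called in the ratio, nor adjusted over the list alone. Of 19 complement genes C8a fell (-0.41, SE 0.09), also adjusted over the list alone, and lost its call without any 1 array but control 4 (camera adjusted p = 0.133 for the list). The complement list passed downward in the Cy5 channel alone, without the filter on dim probes and without control 3 or PFOS 1. Of the 15 settings, 5 ended the call of Psmc2, 3 that of Rps26, 6 that of Uqcrh, 7 that of Rrm2 and 8 that of C8a.

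Markers of liver cell types were read on the same arrays. Hepatocyte markers shifted downward (median -0.11, camera adjusted p = 0.0322, adjusted p = 0.501 with an estimated correlation), with 1 of 12 lower, Ahsg, the plasma glycoprotein fetuin-A (-0.91, SE 0.13), and 3 adjusted over the list alone. Ahsg lost its call with median centring and with scaling between arrays. The list's shift was lost without control 1, control 2, PFOS 2 or PFOS 3, in fry (adjusted p = 0.0838), without background subtraction, with normexp at offset 0 and in the authors' value table, and its median was 0.09 after scaling between arrays. Endothelial markers shifted downward (median -0.44, camera adjusted p = 0.0114, adjusted p = 0.501 with an estimated correlation) with none of 7 called and 3 lower adjusted over the list alone, among them Kdr (-0.48, SE 0.17), Flt4 (-0.44, SE 0.16) and Fcgr2b (-0.46, SE 0.15), and the list did not pass in fry (adjusted p = 0.133). Of 13 macrophage markers 12 lay below 0 and none was called (median -0.22, camera adjusted p = 0.103), Cd5l at -0.78 (SE 0.35) among them. The macrophage list passed downward with median centring, in the Cy5 channel alone, without the filter on dim probes and with slide row as a block. It also passed without control 3, control 4 or PFOS 1 and in slide row 1 alone. In the main fit, 20 of 35 splits gave a camera p as small as the real one. None was called among 11 stellate cell markers (camera adjusted p = 0.627), 5 cholangiocyte markers (0.296), 10 lymphocyte markers (0.662), 4 erythroid markers (0.142) or 3 exocrine pancreas markers (0.758), and adjusted over the list alone 1 cholangiocyte marker, Epcam (0.66, SE 0.18), was higher. Neutrophil markers and adipocyte markers had 2 tested genes each, too few for the list test, and none was called.

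**Figure D4:**
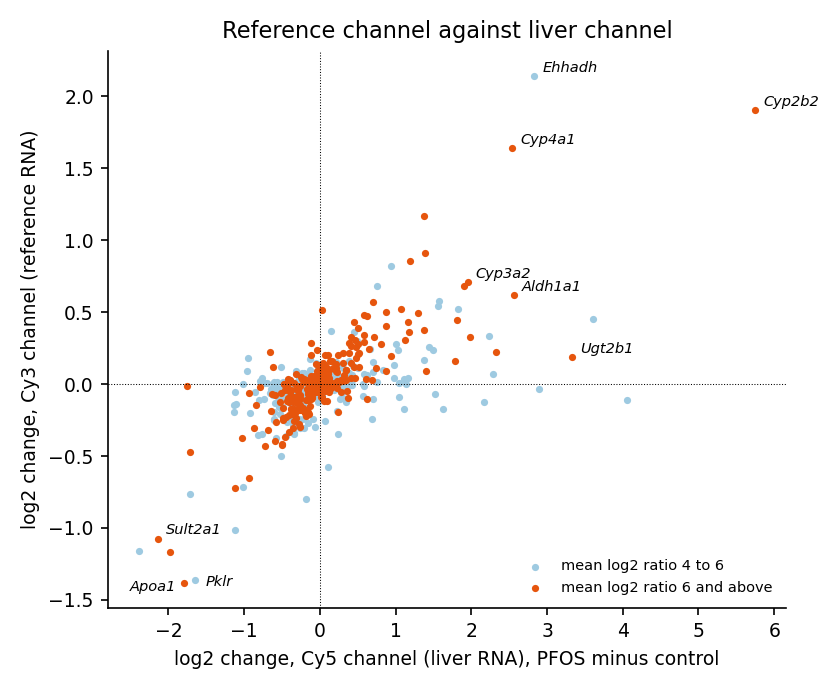
For the tested genes with a mean log2 ratio of at least 4, the log2 change of the Cy3 reference channel on the y axis is set against that of the Cy5 liver channel on the x axis, PFOS minus control, 1 point per gene. The reference is common to all arrays, yet Ehhadh, Cyp4a1 and Cyp2b2 lie high and Apoa1, Pklr and Sult2a1 low on the Cy3 axis, and over genes with a mean log2 ratio of 6 and above the slope is 0.33.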

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

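Among 322 sets of 4 values from a group, 22 had 1 array far from the other 3, where chance would give about 16.1 (1 in 20). All tests of explanations in this part were chosen after the results were seen. In the control group, Hdc stood at a log2 ratio of 1.07 on control 4 against -0.92 to -0.69 on the others, A1bg at 4.81 on control 2 against 1.59 to 2.12, Gadd45b at -2.04, Sc5d at 3.25 and Cfd at -0.25 on control 1. On control 3, Lipc was at 5.64, Nfil3 at 1.10, Serpinc1 at 9.30, Serpina1 at 8.02 and Dio1 at 5.91, the last against 6.06 to 6.09. On control 4, Csf1r was at 1.64 and Flt4 at 1.31, against 2.06 to 2.12 and 1.87 to 1.91. In the PFOS group, Cyp2b21 was at 1.98 on PFOS 4 against 3.25 to 3.39, Tat at 5.89 on PFOS 4 against 5.31 to 5.32 and Acaa1b at 5.48 on PFOS 4. Cry1 was at 0.82 on PFOS 3 against -0.34 to -0.20, Socs3 at -0.46 and Pex11g at 1.17 on PFOS 3, Apoa1 at 6.84, Eno1 at -0.98 and Cpt2 at 3.53 on PFOS 2, and Ndufa5 at 1.05 on PFOS 1.

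Csf1r and Flt4 on control 4 belong to the macrophage and endothelial markers, whose combined median over 20 genes was -0.28 in PFOS. The difference of their means between the groups was -0.33 over arrays, which an exact permutation test of 4 against 4 arrays did not separate from 0 (p = 0.200). With 1 array left out the combined median stayed between -0.48 and -0.202, so no 1 array made its direction. A smaller share of all non-hepatocyte cells should lower stellate cell and cholangiocyte markers too, and their median lay 0.296 higher. The difference of means varied too much between arrays to decide this (0.35, exact permutation p = 0.257). This test over arrays replaced 1 that permuted genes, which are not independent replicates, after that one had argued against a smaller share of these cells. So a lower share of non-hepatocyte cells cannot be told apart from a change in some of them or from no change.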

How the results depend on the processing

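The slide rows taken alone were chosen after the data were seen, and all other settings before. The number of changed genes (602) was 239 with median centring, 268 with slide column as a block, 343 with at least 1.5-fold, 92 in slide row 1, 29 in slide row 2 and 350 to 519 with 1 array left out. Genes higher (277) numbered 129, 138, 166, 41 and 14 in these settings and 166 to 313 with 1 array left out. Genes lower (325) numbered 110, 130, 177, 51 and 15, 200 with scaling between arrays and 175 to 237 with 1 array left out. Fewer arrays or residual degrees of freedom explain part of this by construction for the rows, the block and the left-out arrays, and the stricter criterion does for the fold, while for centring and scaling the cause was not tested. In the other settings the count was 408 to 730, and 229 of the 239 and 244 of the 268 genes were among the 602. Shifted lists (12) numbered 0 with an estimated correlation, 7 with processed signals and 7 in slide row 2, and 8 to 17 elsewhere. A larger estimated correlation cannot be the whole reason for the first. The circadian list, with an estimated correlation of -0.0343 against the preset 0.01, still went from a camera p of 0.0769 to 0.11. The cause was not tested for processed signals. Among called values, 5 signs turned. The apolipoprotein median was 0.0321, the glucose metabolism median 0.0165 and the hepatocyte marker median 0.0894 after scaling between arrays, and with processed signals Sult2a1 was at 0.37 and Cyp4a1 at -0.00479, none of them called. The cause was not tested for the medians. For Sult2a1 and Cyp4a1 the Cy3 signal moved with the Cy5 signal. Of 63 named genes called, 36 were called in all planned settings that tested them and 38 without any 1 array, and 61 kept their sign throughout. Over all tested genes the median change lay between -0.02 and 0.02 in each setting. Cy5 signals near the background limit what dim probes can show.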

Other observations

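The tests of ribosome assembly genes, ATF4 targets, fasting and unnamed features were chosen after the results were seen. So were those of Cy5 brightness and of the Cy3 channel by mean log2 ratio. The splits of the arrays and the Cy3 share were chosen before. Genes of ribosome assembly in the nucleolus, a list written after several had been seen among the rises, had 17 of 96 tested members higher in PFOS and none lower (median 0.25, 88 of 96 above 0). Ppan rose by 0.80 (SE 0.12) on the log2 scale, the nucleolar GTP-binding protein Gnl3 by 0.79 (SE 0.11), Nop58, a core protein of small nucleolar RNA complexes, by 0.67 (SE 0.10), Rrs1 by 0.67 (SE 0.10) and Mybbp1a by 0.55 (SE 0.09). The 79 members that were not called also lay above the other genes (median 0.20, 71 above 0, camera p = 3.47e-14, and p = 0.00885 with an estimated correlation). For the whole list the real split gave the smallest camera p of the 35 splits (5.3e-22), but another split gave 2.29e-16. Camera p-values this small at the preset correlation can thus arise with another grouping of the arrays. Such a grouping can hold part of the diet's difference, so this does not show what chance alone gives. A candidate explanation is that PFOS raised transcripts of much of this machinery, as a hypothesis found and tested on the same arrays. This list was not tested under the other settings or with arrays left out. Nor were the lists of ATF4 targets and fasting-induced genes below.

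Targets of the amino acid response factor ATF4, also listed after the data were seen, had 6 of 33 members higher and 3 lower. Beside Asns, Adm2 rose by 0.80 (SE 0.12) on the log2 scale, Psat1, of serine synthesis, by 0.69 (SE 0.15), Slc3a2, an amino acid transporter subunit, by 0.65 (SE 0.11), Eif4ebp1 by 0.63 (SE 0.12) and Mthfd2 by 0.57 (SE 0.12). Fgf21, Nupr1 (-0.71, SE 0.07) and Atf5 (-0.54, SE 0.12), which ATF4 can also induce, fell. The 27 members not called higher, these 3 falls included, had a median of 0.08 and were not separated from the other genes (camera p = 0.109, and p = 0.157 with an estimated correlation). This test replaced 1 that had left out the 3 falls, in which 21 of 24 members lay above 0 (camera p = 0.00137, and p = 0.0156 with an estimated correlation). Both sets were formed by the change itself. Whether ATF4 targets rose beyond these 6 stays open.

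Fgf21 fell while 8 other PPARA targets were called higher. Longer fasting of the control rats could lower Fgf21 in PFOS by comparison, and fatty acid synthesis genes should then be higher in PFOS. Their median was -0.44 and at most -0.316 with any 1 array left out, but their mean change of -0.46 was not separated from 0 over arrays (exact permutation p = 0.114). The other 12 fasting-induced genes had a median of 0.20, with 9 above 0 and none called (camera p = 0.0194, and p = 0.0767 with an estimated correlation). With Fgf21 included, the camera p of these genes was 0.151. Both lists lay opposite to what longer fasting of the control rats would give, but not all tests separated them. So a difference in feeding cannot be told apart from an effect of PFOS here.

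The number of changed genes was 602 in the real split and at most 5 in the other 34 of the 35 splits of the 8 arrays. So 1 of 35 splits gave as many, which argues against chance at the lowest p these splits allow (exact permutation p = 0.0286). The same held for genes higher (277, 1 of 35, highest other 4) and genes lower (325, 1 of 35, highest other 4). Any effect of the diet stayed in the residual of the other splits, so their counts do not show how many calls chance would give. For the number of shifted lists, 6 of 35 splits gave 12 or more and the highest other gave 16, so this count did not exclude chance. Apart from the real one, these splits kept most control arrays on 1 side. They thus hold part of the diet's difference and cannot show what chance alone gives. Splits with 2 arrays of each diet on both sides gave at most 11, with the diet's effect left in their residual. A difference in Cy5 brightness is argued against as a cause of the changed genes, since the brighter and the dimmer slide row each held 2 arrays of both groups. With each array's Cy5 median as a covariate the 602 genes kept a median of 100% of their change (lowest 91.2%), and 491 of them were still called in limma. Since brightness was nearly balanced between the groups (122 to 159 in control, 116 to 160 in PFOS), this covariate could hardly move the change and adds little. The covariate fit replaced the planned test, the split by slide row, which called 0 genes but left the diet's effect in its residual and so could not decide. A difference in the reference channel is argued against as well for most of them, since over the 602 genes the Cy3 channel moved against the ratio by a median of 0.536% of its change, with quartiles of -3.38% and 4.43%.

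For a few genes the Cy3 signal followed the Cy5 signal between the groups. The slope of Cy3 on Cy5 changes was 0.332 over 261 genes with a mean log2 ratio of 6 and above (r = 0.81 across genes, which are not independent replicates), and 0.0305 over 7069 genes from 0 to 2, which argues against spot size or hybridization strength shared by both channels. The first slope met the bound first set for a fixed leak of Cy5 light into the Cy3 channel, but this test and its bound were replaced after the spot signals were seen. The Cy3 signal of Cyp4a1 rose by 1.09% of its Cy5 rise, 8.05 times the whole Cy3 signal at the brighter Cyp3a2 spots (at most 0.136% of Cy5), and in 46 of 266 genes at least as bright in PFOS the whole Cy3 signal lay below that share, which argues against a fixed leak. What stays open is a cause that differs between probes, such as binding between labelled sample and reference RNA, which was not tested, and ratios may misstate changes of abundant liver transcripts.

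Features without a symbol made up 186 of the 602, 113 of them lower. The falls of more than 1.5 on the log2 scale held 17 such features, led by ENSRNOT00000045517 (-3.14, SE 0.24) and A_64_P114838 (-3.05, SE 0.26). Within groups these 17 deviated together, with a median pairwise correlation of 0.587 against a median of -0.001 and a 95th percentile of 0.0972 in 10000 random sets of as many of the 212 falling genes with a symbol. The random sets were not matched for size of fall or brightness, so they do not show how far strongly falling genes in general deviate together. For most of the 17 features the correlation could come from 1 transcript or family read by several probes, but separate genes under common control stay open. ENSRNOT00000045517 itself deviated against the others (median correlation -0.63). Beside a feature at 4.01 (SE 0.47) whose RefSeq record matched no symbol, rises without a symbol included A_64_P164474 (3.56, SE 0.59) and ENSRNOT00000014739 (3.00, SE 0.42).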
